A study of Homo sapiens with 9 samples.

How the data were processed

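Small RNA libraries of T47D cells were sequenced on an Illumina platform from Trizol-extracted total RNA, per the labels, with 3 libraries each for the scramble control (NC), Si-TINCR-1 and Si-TINCR-2. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, reads were aligned to GRCh38.p12 with Bowtie2, whose version is not given. Per the file headers, each deposited file lists read counts of small RNAs and read classes, and these counts add up to the library total in the header. The smallest count listed was 1 read for known entries and 10 for predicted miRNA and piRNA entries. The same deposited files hold a second value, named TPM by the authors, which equals counts-per-million (CPM) of the whole library in every entry within 0.005 and involves no length scaling. The read counter, the trimming and quality filters and the miRBase release are not given in the sources used here. Reads had been assigned by the authors to 14 exclusive classes, among them mature miRNA, miRNA precursor, predicted miRNA, predicted piRNA, ribosomal, transfer and small nucleolar RNA, repeat, exon, intron and intergenic reads.

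All comparisons of miRNAs used the counts, and the deposited CPM values served as a check of the unit. Of 1807 identifiers listed as mature or hairpin, 44 occurred in both classes and were reduced to the entry with the higher sum. A miRNA absent from a file counted as 0 there. Library totals ran from 18.1 to 21.96 M reads, of which 5.73 to 12.7 M were mature miRNA reads. A floor of 3 counts and all counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. CPM printed for miRNAs refer to the mature miRNA reads of the 745 tested miRNAs after TMM scaling, and reads-per-million (RPM) to all reads of the library.

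Counts were analysed in R 4.3.3 with edgeR 4.0.16. miRNAs were kept by filterByExpr (745 remained), libraries were scaled by the trimmed mean of M-values (TMM), and a model with 1 mean per group over all 9 libraries was tested by the quasi-likelihood F-test. The 4 contrasts were Si-TINCR-1 against NC, Si-TINCR-2 against NC, the mean of both against NC, and Si-TINCR-2 against Si-TINCR-1. All tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The overlap between the siRNAs was set against 100 simulations without an effect that share the NC libraries. Lists of miRNAs were tested on log2 CPM (prior count 2) with camera (preset correlation 0.01) and fry from limma 3.58.1. There were 30 lists, of which 25 had at least 3 tested members. They covered miRNAs that repress EGFR or ERBB genes, miRNAs named as bound by TINCR, families and clusters, breast cell identity, pathways, mirtrons, entries resembling ribosomal or transfer RNA, and markers of blood, endothelium, fibroblasts, striated muscle, liver and neural cells. Groups, contrasts, tests of miRNAs and of lists, the lists, the rule for named miRNAs and the alternatives were fixed before the data were examined, except for scaling by whole library totals and fry without miR-205-5p, which were added afterwards.

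By the rule for named miRNAs, the text gives for each contrast with NC the 10 largest rises and the 10 largest falls among miRNAs that passed, had a mean of at least 10 CPM and did not overlap between groups, filled to 5 by unadjusted p where fewer than 5 passed. It further gives every tested member of the EGFR/ERBB and TINCR lists, 2 to 4 members of other lists by unadjusted p, the 5 most abundant miRNAs, and the 5 smallest adjusted p-values between the siRNAs. The shared rises and falls named beside the overlap were chosen after their values were seen.

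Read classes, the let-7 family share, Y RNA and other small RNA, and reads at the TINCR gene were compared by exact permutation of the 9 libraries, 6 against 3 (84 splits). These comparisons were chosen after the data were seen. Gene positions came from GENCODE 29. Mature let-7 sequences were taken from the hairpins in GENCODE 29, with positions counted from 1 at the 5′ end. These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

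Alternatives were DESeq2 1.42.0 in place of edgeR, RLE size factors, TMM without the 5 most abundant miRNAs, no filter, a filter at a mean of 10 CPM, duplicate entries summed, replicate number as a block, only the 6 libraries compared, both siRNAs as 1 group, camera with an estimated correlation, each library left out in turn, and scaling by whole library totals. Alternatives for normalised values were not run, because the files hold counts. Replicate numbers were not treated as pairs: of 9 pairs of libraries with the same number in different groups, the correlation of deviations from the group mean ran from −0.19 to 0.23, and 2 of 9 libraries matched best with their own number. The procedure was tested on simulated data, 5 draws in which 200 of 745 miRNAs changed. It recovered 40.6% of 2-fold and 88.8% of 4-fold changes for Si-TINCR-1, 40.2% and 88.2% for Si-TINCR-2 and 53.2% and 93.0% for the mean of both, with 2.92 to 3.60% false calls. In these draws nothing differed between the siRNAs, and none was called there.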

Results

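Small RNA was sequenced from T47D cells, an oestrogen receptor-positive luminal breast cancer line, after transfection with a scramble control (NC) or with 1 of 2 siRNAs against TINCR, a long non-coding RNA first described in the differentiation of epidermal cells. The title of the series places TINCR in a loop with EGFR signalling, and the comparisons ask which microRNAs (miRNAs) changed when TINCR was targeted. Each of the 3 groups held 3 libraries, and the protocol in the labels has cells harvested 48 h after lipid transfection. The libraries held 18.1 to 21.96 M (mega) annotated reads each. Reads of mature miRNAs numbered 12.7, 12.3 and 12.3 M in NC, 6.06, 6.90 and 5.83 M with Si-TINCR-1, and 7.10, 6.55 and 5.73 M with Si-TINCR-2. Between 1296 and 1449 mature miRNAs had at least 1 read per library, and 745 were abundant enough to test. A floor of 3 counts corresponded to 0.255 to 0.530 CPM, which are counts-per-million of mature miRNA reads scaled by the trimmed mean of M-values (TMM). Values are mean ± SD of 3 libraries per group, fold changes are on the log2 scale ± SE, and adjusted p-values come from edgeR's two-sided quasi-likelihood test with Benjamini-Hochberg adjustment over the 745 miRNAs. Nothing in the labels states that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

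The target was examined first. The libraries hold small RNA, so the level of the TINCR transcript was not measured and the extent of its knockdown is not known from these data. Short reads placed within the TINCR gene were nevertheless listed in all 6 siRNA libraries and in no NC library. They formed 12 predicted piRNA entries between 5558333 and 5558482 on the minus strand of chromosome 19 (GRCh38), inside exon 3, the last exon of transcript TINCR-201, where the files also note a LINE/L2 repeat. The reads numbered 6204, 3113 and 1374 in the Si-TINCR-1 libraries and 2942, 7361 and 12737 in the Si-TINCR-2 libraries. As reads-per-million of the library (RPM), these were 181.9 ± 127 and 387 ± 255. No predicted entry was listed with fewer than 10 reads. If 10 was the minimum for listing, each NC library could hold up to 108 unlisted reads of these 12 entries. That is 5.07 RPM on average and 5.22 RPM at most. For these entries, the mean of the 6 siRNA libraries was then at least 56.2-fold above that average, and the lowest library at least 14.51-fold above the most (exact permutation p = 0.0476 with NC taken as 0, two-sided). The bound does not cover NC reads at this position that were placed in another read class, such as exon or repeat. Of the 12 entries, 11 were listed in both siRNA groups.

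**Figure D1:**
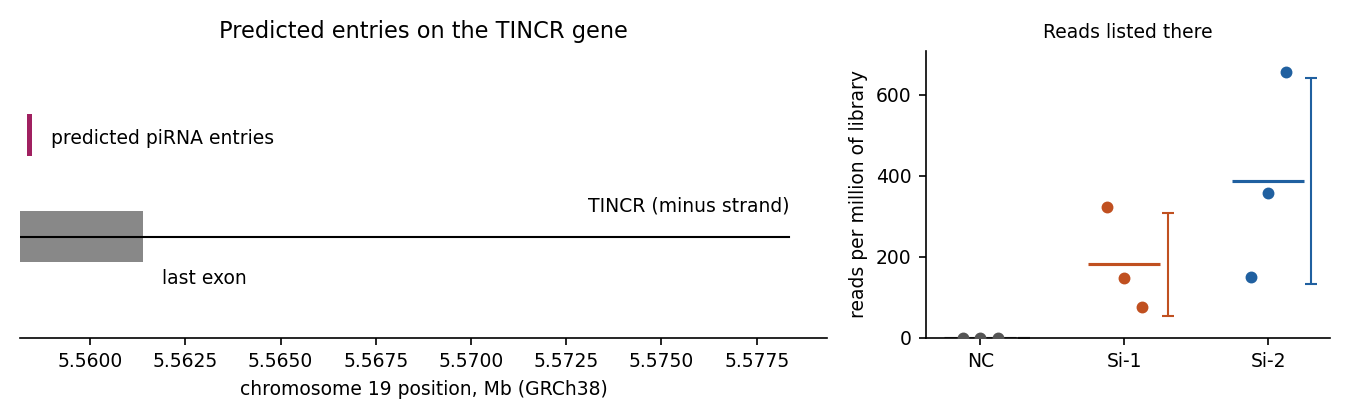
The left panel draws the TINCR gene on chromosome 19 (Mb, GRCh38) with its last exon and the predicted piRNA entries, and the right panel plots RPM at these entries, each dot a library, the horizontal line the mean and the bar the SD of NC, Si-TINCR-1 (Si-1) and Si-TINCR-2 (Si-2). All 3 NC libraries are listed at 0, and the 6 siRNA libraries lie between 75.8 and 656 RPM.

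The siRNA libraries also held a different mixture of small RNA. Mature miRNAs made up 58.3 ± 0.958% of the reads in NC, 32.1 ± 0.576% with Si-TINCR-1 and 32.4 ± 3.29% with Si-TINCR-2 (exact permutation p = 0.0119 for 6 libraries against 3, the smallest that 84 splits can give; adjusted over 14 read classes, 0.0185). The reads that filled the difference came from several kinds of RNA. Intergenic reads rose from 15.8 ± 1.19% to 29.9 ± 1.57% and 28.3 ± 2.14%, repeat reads from 7.75 ± 0.571% to 13.8 ± 0.638% and 14.5 ± 0.813%, and intron reads from 7.84 ± 0.956% to 11.4 ± 0.308% and 11.2 ± 0.702%. Predicted miRNA reads rose from 0.154% to 0.751% and 0.816%. Other small non-coding RNA, which is mostly Y RNA, rose from 0.479 ± 0.0288% to 1.53 ± 0.433% and 2.20 ± 0.175%. Transfer RNA reads rose from 0.0765% to 0.266% and 0.239%, with the same exact p of 0.0119 in each of these 6 classes. Precursor reads fell from 2.24% to 1.39% and 1.37% (exact p = 0.0119). Ribosomal RNA reads rose from 0.771 ± 0.0811% to 1.548 ± 0.460% and 1.20 ± 0.0378% (exact permutation p = 0.0238, adjusted 0.0333). Exon reads were 3.17%, 3.22% and 3.65% of the libraries (exact p = 0.417). With 3 libraries against 3, no exact p can fall below 0.1. Every comparison of miRNAs below is relative to the other miRNAs in the same library, and this loss of mature reads accompanies each comparison with NC.

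**Figure D2:**
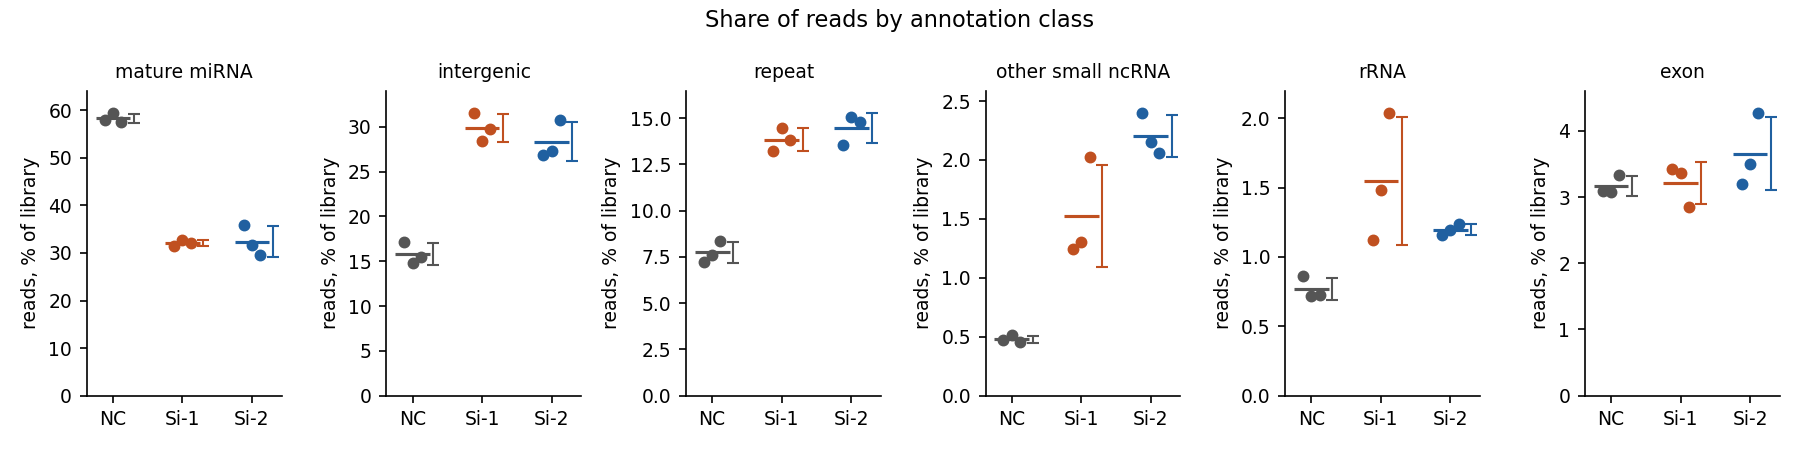
Share of each library's reads (percent) in 6 read classes, with dots for libraries, horizontal lines for means and bars for SD, for NC, Si-TINCR-1 (Si-1) and Si-TINCR-2 (Si-2). The mature miRNA share lies between 57.6% and 59.4% in NC and between 29.5% and 36.0% in the 6 siRNA libraries.

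The 5 with the highest mean level were miR-21-5p, an oncogenic miRNA abundant in breast cancer cells, miR-27a-3p, let-7i-5p, miR-24-3p and miR-100-5p, and the top 5 of each library took 39.1 to 43.8% of its mature miRNA reads. miR-21-5p stood at 219604 CPM in NC, 206690 CPM with Si-TINCR-1 and 196311 CPM with Si-TINCR-2 (log2 fold change for the mean of both siRNAs −0.12, adjusted p = 0.592). None of the 5 passed the test for the mean of both siRNAs relative to other miRNAs. When libraries were scaled by all their reads, miR-21-5p (−0.80), let-7i-5p (−0.98), miR-100-5p (−0.80) and miR-27a-3p (−0.60, against 0.06 with adjusted p = 0.859) passed as falls, and miR-24-3p (−0.59) did not. The median of all tested miRNAs was −0.68 in that scaling.

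Si-TINCR-1 raised 22 miRNAs, 7 of them entries that resemble ribosomal or other small RNA, miR-4532 and miR-3656 among these, and lowered members of the let-7 family, which repress RAS and other growth genes. miR-3182, encoded within CDH13 on chromosome 16 (83508346 to 83508408, plus strand), rose from 1.51 ± 0.576 to 76.7 ± 14.4 CPM (log2 fold change 5.66 ± 0.33, adjusted p = 3.28e-05). miR-4532 rose from 401 ± 107 to 4016 ± 458 CPM (3.33 ± 0.23, adjusted p = 6.06e-05), and miR-451a, a miRNA of red blood cells that matures without Dicer, from 28.2 ± 10.1 to 104 ± 20.6 CPM (1.88 ± 0.29, adjusted p = 0.00542). let-7b-5p fell from 44575 ± 7232 to 11697 ± 1940 CPM (−1.93 ± 0.18, adjusted p = 0.000292), and let-7c-5p from 5269 ± 1040 to 1062 ± 302 CPM (−2.31 ± 0.24, adjusted p = 0.000699). In all, 38 of the 745 miRNAs passed with edgeR, 22 higher and 16 lower. The unadjusted p was under 0.05 for 116 miRNAs, where 37.25 would pass by chance, and DESeq2 called 47.

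The other large rises with Si-TINCR-1 among miRNAs of at least 10 CPM were those of miR-4492 (3.61 ± 0.27), miR-3656 (3.42 ± 0.43), miR-4448 (3.04), miR-4488 (2.73), miR-4516 (2.50), miR-3960 (2.17) and miR-619-5p (1.69 ± 0.23). Adjusted p-values for these 7 lay between 9.87e-05 for miR-4492 and 0.0269 for miR-4516. Of the falls at that level, that of miR-378e was the largest, from 683 ± 452 to 12.6 ± 6.80 CPM (−5.76 ± 1.21, adjusted p = 0.0269). let-7a-5p (−1.96 ± 0.28, from 67747 ± 24338 to 17456 ± 5160 CPM), let-7d-5p (−1.58 ± 0.23) and let-7e-5p (−1.26 ± 0.24) fell as well, with adjusted p = 0.00432, 0.00432 and 0.0155. The remaining falls were miR-1908-5p (−1.27 ± 0.21, adjusted p = 0.00817), miR-1247-5p (−1.09 ± 0.21, adjusted p = 0.0155), miR-125a-5p, a repressor of ERBB2 and ERBB3 (−0.75 ± 0.17, adjusted p = 0.0400), and miR-204-5p (−0.63 ± 0.14, adjusted p = 0.0291). With 1 library left out, miR-378e no longer passed without NC replicate 2 (adjusted p = 0.0686) or without any 1 Si-TINCR-1 library (0.0923 to 0.123), miR-3960 without NC replicate 3 (0.0802), miR-4516 without NC replicate 2 (0.102) or Si-TINCR-1 replicate 1 or 3 (0.0580 and 0.0858), and miR-1247-5p without any 1 Si-TINCR-1 library (0.0548 to 0.0672). miR-125a-5p passed only with NC replicates 2 and 3, Si-TINCR-1 replicates 2 and 3 and all Si-TINCR-2 libraries present (up to 0.138 otherwise), and miR-204-5p lost its call without any 1 library other than NC replicate 1 (0.0502 to 0.114). With the replicate number as a block, the calls for miR-378e (0.0802), let-7e-5p (0.0759), miR-1247-5p (0.0525), miR-3960 (0.0560), miR-125a-5p (0.105) and miR-204-5p (0.0918) were lost. In a fit of only the 6 libraries compared, let-7e-5p (0.0586), miR-1247-5p (0.0731), miR-125a-5p (0.0969) and miR-204-5p (0.119) no longer passed, and without a filter miR-125a-5p (0.0705) and miR-204-5p (0.181) did not.

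Si-TINCR-2 raised the same leading miRNAs. miR-3182 reached 108 ± 23.4 CPM (6.15 ± 0.34, adjusted p = 1.87e-05), miR-4532 reached 3586 ± 338 CPM (3.16 ± 0.23, adjusted p = 5.47e-05) and miR-451a reached 113 ± 15.2 CPM (2.003 ± 0.30, adjusted p = 0.00344). miR-619-5p, encoded within SSH1 on chromosome 12, rose from 2.71 ± 0.864 to 37.2 ± 0.835 CPM (3.77 ± 0.24, adjusted p = 3.09e-05). miR-22-3p, reported to repress the oestrogen receptor gene ESR1, fell from 14976 ± 3340 to 5528 ± 368 CPM (−1.44 ± 0.21, adjusted p = 0.00325). In total 49 miRNAs passed with edgeR, 30 higher and 19 lower, 145 had an unadjusted p under 0.05, and DESeq2 called 71. The edgeR count was 30 without NC replicate 3, 29 without Si-TINCR-2 replicate 1 and 28 without Si-TINCR-2 replicate 2.

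The further rises with Si-TINCR-2 were miR-4492 (3.76), miR-3656 (3.73), miR-4448 (3.19), miR-4488 (3.18), miR-4516 (2.66) and miR-3960 (2.19), with adjusted p-values from 5.47e-05 to 0.0180. The let-7 members fell by less than with the first siRNA, let-7c-5p to 1986 ± 178 CPM (−1.41 ± 0.23), let-7a-5p to 28021 ± 1666 CPM (−1.27 ± 0.27), let-7b-5p to 21608 ± 2499 CPM (−1.04 ± 0.17) and let-7d-5p to 6553 ± 1058 CPM (−0.93 ± 0.23), with adjusted p = 0.00684, 0.0232, 0.00684 and 0.0462. None of these differences between the siRNAs passed with edgeR, and DESeq2 called that of let-7b-5p (adjusted p = 0.00683). miR-1247-5p (−1.40 ± 0.21, adjusted p = 0.00344), miR-1260b (−1.43 ± 0.33, adjusted p = 0.0372), miR-1908-5p (−1.15, adjusted p = 0.0130), miR-338-5p (−0.89 ± 0.18, adjusted p = 0.0194) and miR-7706 (−0.81 ± 0.20, adjusted p = 0.0453) fell too. With 1 library left out, let-7a-5p lost its call without Si-TINCR-1 replicate 2 (0.0584) or any 1 Si-TINCR-2 library (0.106 to 0.108), let-7b-5p and let-7c-5p lost theirs without Si-TINCR-2 replicate 2 (0.0532 and 0.0516), let-7d-5p and miR-7706 without any 1 library other than Si-TINCR-1 replicate 3 (0.0574 to 0.189 and 0.0517 to 0.185), miR-3960 without NC replicate 3 (0.0668) and miR-4516 without NC replicate 2 (0.0549). miR-1908-5p and miR-338-5p were lost without NC replicate 2 or 3 or Si-TINCR-2 replicate 1 or 2 (0.0540 to 0.0842 and 0.0567 to 0.0852), miR-338-5p also without Si-TINCR-2 replicate 3 (0.0871), and miR-1260b without any 1 library other than NC replicate 1, Si-TINCR-1 replicate 3 or Si-TINCR-2 replicate 2 (0.0528 to 0.158). The replicate number as a block ended the calls for let-7a-5p (0.0634), let-7d-5p (0.0882), miR-1260b (0.0523), miR-338-5p (0.0634) and miR-7706 (0.0798). miR-1260b and miR-7706 did not pass in a fit of only the 6 libraries (0.0728 each), and let-7d-5p, miR-1260b and miR-7706 did not with a mean of at least 10 CPM (0.0585, 0.0573 and 0.0528). let-7d-5p was lost with RLE size factors (0.0504) and, as was miR-7706, with scaling that leaves out the 5 most abundant miRNAs (0.0590 and 0.0525), and miR-7706 was lost without a filter (0.0514).

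Both siRNAs carry the same treatment label, so their mean against NC was taken as the contrast for the shared treatment. It cannot separate the targeting of TINCR from other differences common to all siRNA libraries, such as their lower mature miRNA share. By this contrast 28 miRNAs rose and 25 fell, 53 in all with edgeR, where 132 had an unadjusted p under 0.05 and DESeq2 called 67. Without NC replicate 3 the edgeR count was 35. miR-3182 (5.91 ± 0.33, adjusted p = 1.88e-05), miR-4492 (3.68, adjusted p = 5.42e-05), miR-4532 (3.24 ± 0.21, adjusted p = 4.54e-05) and miR-619-5p (2.73, adjusted p = 0.000108) had the smallest adjusted p-values among the named rises. miR-3656 (3.57), miR-4448 (3.12), miR-4488 (2.96), miR-4516 (2.58), miR-3960 (2.18) and miR-451a (1.94 ± 0.27) rose with adjusted p-values from 0.000468 to 0.0120. miR-3960 lost its call without NC replicate 3 (adjusted p = 0.0534) and miR-4516 without NC replicate 2 (0.0536). Among miRNAs of at least 10 CPM the falls were led by miR-378e (−4.59 ± 0.86, adjusted p = 0.0113), whose level per library was 965, 921 and 162 CPM in NC, 7.03, 20.2 and 10.6 CPM with Si-TINCR-1, and 19.5, 11.1 and 160 CPM with Si-TINCR-2. With the replicate number as a block the call for miR-378e was lost (adjusted p = 0.0541). Other miR-378 entries did not share so large a fall when libraries were scaled by all their reads. There miR-378e was at −5.34 and miR-378i at 9.29 (edgeR adjusted p = 0.0259). Of the rest, miR-378b (3.43) and miR-378g (1.63) were positive without passing, while miR-378a-3p (−0.55), miR-378a-5p (−0.63), miR-378c (−0.31) and miR-378d (−0.13) were negative. Whether reads were assigned differently among these entries was not tested. miR-1247-5p (−1.24, adjusted p = 0.00238), miR-1908-5p (−1.21, adjusted p = 0.00297), miR-22-3p (−1.11 ± 0.17, adjusted p = 0.00359) and miR-3940-3p (−1.02 ± 0.22, adjusted p = 0.0215) also fell. The call for miR-3940-3p was lost without NC replicate 1 or 2, Si-TINCR-1 replicate 1 or 2, or Si-TINCR-2 replicate 1 or 2 (adjusted p = 0.0553 to 0.0894).

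Within the let-7 and miR-98 family, 5 of 9 members fell and none rose for the mean of both siRNAs (5 lower adjusted over the list alone). let-7c-5p (−1.86 ± 0.19), let-7a-5p (−1.62 ± 0.22), let-7b-5p (−1.49 ± 0.14), let-7d-5p (−1.26 ± 0.19) and let-7e-5p (−1.10 ± 0.20) passed with adjusted p-values from 0.000354 to 0.00884. let-7f-5p (−0.21), let-7g-5p (−0.20), let-7i-5p (−0.30) and miR-98-5p (0.02) did not pass relative to the other miRNAs, but all 4 fell when libraries were scaled by all their reads (−0.89, −0.88, −0.98 and −0.66). The median of all tested miRNAs in that scaling was −0.68. The 5 lower members held 57.5 ± 0.509% of the family's reads in NC, 29.7 ± 2.44% with Si-TINCR-1 and 42.4 ± 0.630% with Si-TINCR-2, a share that needs no scaling between libraries. These 5 members were picked because they fell in the same libraries, so the share is descriptive. The family was lower than other miRNAs by the camera set test (adjusted p = 0.000150), a call lost with adjusted p = 0.883 with an estimated correlation. With Si-TINCR-1 alone 5 members fell (camera adjusted p = 5.16e-05, adjusted p = 0.801 with an estimated correlation), and with Si-TINCR-2 alone 4 fell, or 5 adjusted over the list alone (camera adjusted p = 0.00141, adjusted p = 0.874 with an estimated correlation). The passenger (3p) arms of the same genes had a median log2 fold change of 0.20 over 6 arms, from −0.48 to 0.77, which turned to −0.48, from −1.14 to 0.09, when libraries were scaled by all their reads, with 3 arms then passing as lower. In that scaling the 5 lower 5p arms ran from −2.54 to −1.78. These members fell in the same libraries in which all mature miRNAs made up 32.2% of reads instead of 58.3%.

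**Figure D3:**
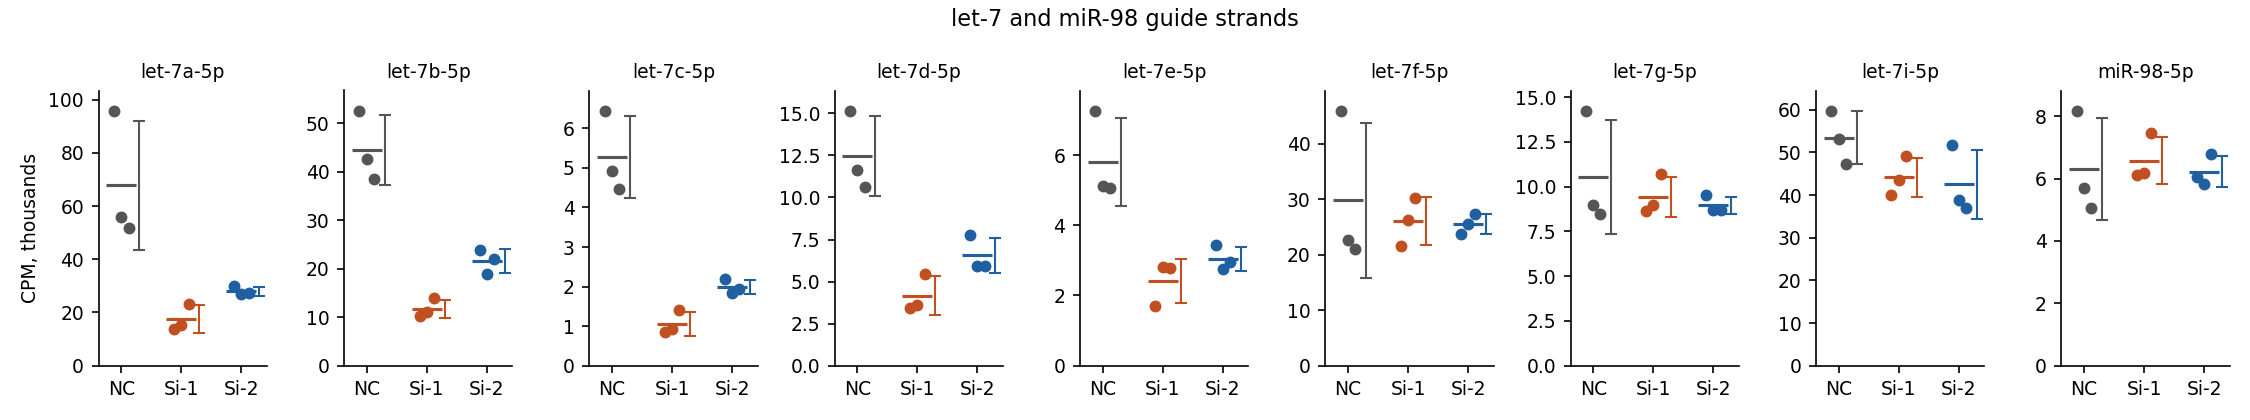
Level of the 9 let-7 and miR-98 members in kilo-CPM, with dots for libraries, horizontal lines for means and bars for SD of NC, Si-TINCR-1 (Si-1) and Si-TINCR-2 (Si-2). let-7a-5p went from a mean of 67747 CPM in NC to 17456 and 28021 CPM, while let-7i-5p (53450, 44178 and 42479 CPM) with let-7f-5p, let-7g-5p and miR-98-5p did not pass the test unless libraries were scaled by all their reads, which made these 4 lower as well. That scaling put the median of all tested miRNAs at −0.68.

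Entries whose sequence resembles ribosomal, transfer or other small RNA were listed as a sign of RNA quality. Of 20 tested, 7 rose and 1 fell for the mean of both siRNAs (8 and 1 adjusted over the list alone). miR-3656 (3.57 ± 0.41), miR-663a (3.33 ± 0.43, adjusted p = 0.00207), miR-4532 (3.24 ± 0.21) and miR-3648 (2.97 ± 0.24, adjusted p = 0.000117) rose the most, and miR-1260b fell (−1.10 ± 0.27, adjusted p = 0.0438). That last call was lost without any 1 library other than NC replicate 1 or Si-TINCR-2 replicate 2 (adjusted p = 0.0591 to 0.169), with the replicate number as a block (0.0701), with a mean of at least 10 CPM (0.0725) and with both siRNAs as 1 group (0.0926). The camera test gave adjusted p = 0.000398 for the list, and adjusted p = 0.498 with an estimated correlation. For Si-TINCR-1 the list had 7 higher and 0 lower members (8 higher adjusted over the list alone; camera adjusted p = 0.000465, adjusted p = 0.773 with an estimated correlation), and for Si-TINCR-2 it had 7 and 1 (camera adjusted p = 0.00141, adjusted p = 0.431 with an estimated correlation). Ribosomal and transfer RNA reads made up larger shares of the same libraries.

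The miRNAs reported to repress EGFR, ERBB2 or ERBB3 did not differ as a group from other miRNAs by the camera test (adjusted p = 0.735). The fry test, which asks whether a list's members move on balance one way and does not compare them with other miRNAs, passed for the mean of both siRNAs (adjusted p = 0.0253) and with Si-TINCR-2 (0.0430), but not with miR-205-5p left out (0.990 and 0.994). Of 14 tested, 2 fell and none rose (the same 2 adjusted over the list alone). These were miR-205-5p and miR-125a-5p. miR-205-5p, a miRNA of basal mammary cells that represses ERBB3, had 76, 53 and 54 counts in NC, 0, 1 and 2 with Si-TINCR-1 and 0 in all 3 Si-TINCR-2 libraries (adjusted p = 0.000825). Its level was 5.33 CPM in NC, a ratio of 0.0284 with Si-TINCR-1 (95% exact Clopper-Pearson counting interval 0.00581 to 0.0844) and at least 11.8-fold lower with Si-TINCR-2, with 3 counts per library as the floor. miR-125a-5p stood at 2130 ± 139 CPM in NC, 1264 ± 180 CPM with Si-TINCR-1 and 1424 ± 176 CPM with Si-TINCR-2 (−0.67 ± 0.14, adjusted p = 0.0247), a call lost without NC replicate 2 or 3, Si-TINCR-1 replicate 2, or Si-TINCR-2 replicate 1 or 3 (adjusted p = 0.0672 to 0.103) and with the replicate number as a block (0.0701). miR-7-5p, a direct repressor of EGFR, had a value of 0.32 ± 0.14 (adjusted p = 0.285), which became −0.36 with scaling by all reads. With Si-TINCR-1 alone its value was 0.56 ± 0.16 (adjusted p = 0.117, and 0.0368 adjusted over the list alone), so that list had 0 higher and 2 lower members, or 1 and 2 adjusted over the list alone. The other values for the mean of both siRNAs were 0.36 for miR-491-5p, −0.32 for miR-146b-5p, −0.31 for miR-503-5p, 0.20 for miR-128-3p, 0.19 for miR-146a-5p, 0.18 for miR-193a-3p, −0.11 for miR-331-3p, 0.08 for miR-542-5p, −0.08 for miR-27b-3p, 0.06 for miR-27a-3p and 0.02 for miR-125b-5p, all with adjusted p of 0.278 or more. The list's median was 0.04 and its mean −0.49 (median 0.04 and mean −0.32 with miR-205-5p at its bound), and the camera test pointed down.

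Among 8 tested miRNAs that studies name as bound by TINCR, 1 fell and none rose (2 lower adjusted over the list alone; camera adjusted p = 0.735, pointing down, with a median of 0.01 and a mean of −0.51). The one that fell was miR-375, a miRNA of luminal breast cells, with 82, 45 and 46 counts in NC, 3, 5 and 8 with Si-TINCR-1 and 6, 3 and 3 with Si-TINCR-2 (−2.81 ± 0.37, adjusted p = 0.00218). miR-107 had a value of −1.70 ± 0.53 (adjusted p = 0.111, and 0.0413 adjusted over the list alone), but NC replicate 1 stood apart at 175 CPM against 25.9 and 32.0 CPM in the other NC libraries, and it passed without NC replicate 2 (adjusted p = 0.0464), without a filter (0.0419) and with DESeq2 (0.0193). The values of miR-7-5p and miR-503-5p are those given with the EGFR list. The values of miR-589-3p (0.26 ± 0.44), miR-199a-5p (0.19 ± 0.27), miR-125b-5p (0.02 ± 0.20) and miR-31-5p (adjusted p = 0.995) did not pass.

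The lists for breast cell identity each held 1 or 2 calls. In the epithelial list (12 tested) and the list of miRNAs higher in oestrogen receptor-positive cells (9 tested), miR-375 fell and nothing else passed, also adjusted over the list alone (camera adjusted p = 0.735 and 0.750). Among 8 tested miRNAs of basal cells or reported to repress ESR1, miR-205-5p and miR-22-3p fell and none rose (1 higher and 2 lower adjusted over the list alone, the higher being miR-155-5p at 0.69 ± 0.22, adjusted p = 0.134). That list's camera adjusted p was 0.596 (fry 0.0253, and 0.667 without miR-205-5p), its median −0.12 and its mean −0.89 (−0.12 and −0.60 with miR-205-5p at its bound). None of 5 tested members of the miR-200 family, which maintains the epithelial state, passed (camera adjusted p = 0.895, pointing down, with a median of −0.01 and a mean of 0.02), and miR-200c-3p had 313 ± 16.9, 279 ± 60.4 and 298 ± 46.8 CPM in the 3 groups.

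Markers of other cell types moved in part. Of 4 tested blood miRNAs, miR-451a (1.94 ± 0.27) and miR-223-3p, a miRNA of myeloid cells, rose (2 adjusted over the list alone). miR-223-3p had 17, 10 and 6 counts in NC, 25, 29 and 53 with Si-TINCR-1 and 75, 114 and 43 with Si-TINCR-2 (3.04 ± 0.49, adjusted p = 0.00463). The values of miR-486-5p (0.10, adjusted p = 0.816) and miR-150-5p (0.09, adjusted p = 0.953), also of blood, did not pass, and that of miR-486-5p became −0.58 with scaling by all reads. The camera adjusted p for blood was 0.0847, with 0.498 as the adjusted p with an estimated correlation (fry 0.00971, up). No member passed among 4 fibroblast and smooth muscle miRNAs (camera adjusted p = 0.877, pointing down, with a median of 0.09 and a mean of −0.01), 6 neural miRNAs (0.735), 2 endothelial miRNAs (miR-126-3p −0.30, adjusted p = 0.278) or 2 miRNAs of striated muscle. The liver miRNA miR-122-5p, the only 1 tested of its list, had a value of 1.24 ± 0.40 (adjusted p = 0.123). Its edgeR p of 0.0121 is unadjusted, since adjustment over a list of 1 changes nothing.

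In the remaining lists 3 miRNAs passed. Of 17 miRNAs repressed by MYC, miR-22-3p fell (1 adjusted over the list alone, camera adjusted p = 0.735). Of 11 mirtrons, which are freed by the spliceosome, miR-3940-3p fell (1 adjusted over the list alone, camera adjusted p = 0.838). Of 2 tested members on the list for the imprinted DLK1-DIO3 cluster on chromosome 14, miR-127-3p rose (2.78 ± 0.39, adjusted p = 0.00238) from 0.705 CPM in NC to 3.46 and 7.02 CPM, and miR-411-5p had a value of 2.02 (adjusted p = 0.111, so 2 higher adjusted over the list alone). miR-1247-5p, encoded within DIO3OS on the same chromosome and not on that list, fell (−1.24, edgeR adjusted p = 0.00238). Nothing passed, in either adjustment, among the miR-17-92 clusters (10 tested, camera adjusted p = 0.844, pointing down with a median of −0.07 and a mean of 0.06), the miR-15/16 family (7 tested, 0.735), the miR-424 cluster on chromosome X (8 tested, 0.735), miRNAs induced by p53 (6 tested, 0.838, pointing up with a median of 0.17 and a mean of −0.17), miRNAs of invasion (9 tested, 0.735), miRNAs induced by NF-kB or interferon (9 tested, 0.838, pointing down with a median of −0.01 and a mean of 0.01), the miR-29 (3 tested, 0.735), miR-30 (5 tested, 0.834) and miR-181 (4 tested, 0.735) families, the miR-23/27/24 clusters (11 tested, 0.891, pointing down with a median of 0.06 and a mean of 0.09), the chromosome 19 cluster (4 tested, 0.722) or the 2 tested miRNAs of hypoxia. In the miR-183 cluster (6 tested, camera adjusted p = 0.722), none passed over all miRNAs and 1 did adjusted over the list alone, miR-96-3p (0.85 ± 0.23, adjusted p = 0.0736, with 0.0212 without Si-TINCR-1 replicate 1, 0.0436 with a mean of at least 10 CPM and 0.0278 with DESeq2). Of the 25 lists large enough to test, 2 passed with camera, let-7 and the entries that resemble other RNA, and 0 did with an estimated correlation. By fry 5 passed for the mean of both siRNAs, let-7 (adjusted p = 0.0253, down), the entries that resemble other RNA (0.00335, up), blood (0.00971, up), and EGFR and ERBB with basal (0.0253 each), of which the last 2 did not pass without miR-205-5p.

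The responses to the separate siRNAs overlapped. Of the 38 and 49 miRNAs called, 29 passed with both, 19 higher and 10 lower, and 0 passed in opposite directions. Independent lists of these sizes would share 0.886 higher and 0.408 lower miRNAs. Besides those already named, the shared rises included miR-663a (3.16 and 3.49), miR-3648 (2.86 and 3.07), miR-223-3p (2.54 and 3.55), miR-16-2-3p (1.09 and 1.37) and miR-4521 (1.27 and 1.10), and the shared falls included miR-375 (−2.58 and −3.04). Across the 745 miRNAs, which are not independent replicates, the log2 fold changes of both siRNAs had a Pearson correlation of 0.76. Both contrasts use the same NC libraries, which alone gave a correlation of 0.174 to 0.641 (mean 0.462) in 100 simulations without any effect, and no shared calls in any of them. The correlation was 0.60 without Si-TINCR-1 replicate 1.

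**Figure D4:**
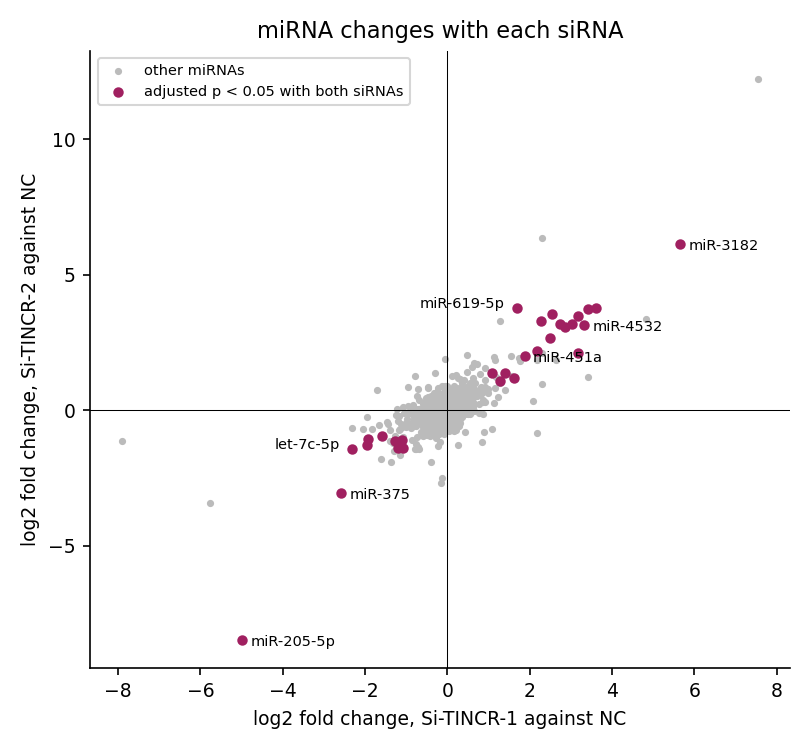
Log2 fold change against NC with Si-TINCR-1 (horizontal) and with Si-TINCR-2 (vertical) for the 745 tested miRNAs, each point a miRNA and coloured points the 29 that passed with both siRNAs. The coloured points lie in the upper right (19) and lower left (10), from miR-3182 (5.66 and 6.15) to miR-205-5p, whose fitted value with Si-TINCR-2 rests on 0 counts.

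A direct comparison of Si-TINCR-2 with Si-TINCR-1 asked whether the siRNAs differed in effect. miR-619-5p was the 1 miRNA to pass with edgeR, at 37.2 ± 0.835 CPM with Si-TINCR-2 against 8.76 ± 0.710 CPM with Si-TINCR-1 (2.09 ± 0.22, adjusted p = 0.00475). The call was lost without Si-TINCR-1 replicate 1 (adjusted p = 0.0510) or replicate 2 (0.0595). At an unadjusted p under 0.05 there were 86 miRNAs, and DESeq2 called 10, the next 4 among them. The next 4 by adjusted p were miR-487a-5p (0.202 against 3.62 CPM, 4.06 ± 0.69, adjusted p = 0.0744), miR-548au-5p (2.89 against 9.26 CPM, 1.67, adjusted p = 0.0744), let-7b-5p (11697 against 21608 CPM, 0.89 ± 0.17, adjusted p = 0.107) and miR-548an (1.001 against 4.16 CPM, 2.03, adjusted p = 0.107), the first value of each pair from Si-TINCR-1. The Si-TINCR-1 level of miR-487a-5p lay below the floor of 3 counts, 0.421 to 0.530 CPM in those libraries, so the size of its difference is uncertain. Without NC replicate 3 in the shared estimate of spread, miR-548au-5p passed (adjusted p = 0.0280). In a fit of only the 6 libraries compared, miR-487a-5p, miR-548au-5p and miR-548an passed (0.0481 each), and without a filter miR-487a-5p did (0.0336).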

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

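The tests of explanations and the other splits in this part were chosen after the results were seen, while the contrasts, counts and list tests they refer to were planned. Most of the values come from reads outside the mature miRNAs, which no comparison of miRNAs uses, and are given because they stood higher in the siRNA libraries than in NC. Positions are those of GRCh38.

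The first pattern joins the rise of entries resembling other RNA, the rise of Y RNA, ribosomal and transfer RNA fragments, and the lower share of mature miRNA. Y RNA, a small RNA bound by the Ro protein, rose 5.87-fold in RPM (2594 ± 61.0 in NC, 15223 ± 4674 over 6 siRNA libraries), 5.8S ribosomal RNA 2.81-fold and transfer RNA 3.30-fold (exact permutation p = 0.0119, 0.0238 and 0.0119). A loss of mature miRNA alone would raise every other class by 1 factor, but per mature read Y RNA rose 6.44-fold even from the highest NC to the lowest siRNA library, above the highest value of 2.799 for exon reads, which argues against it as the whole cause. More fragments of long RNA of every kind stay possible and undecided, since the 1.80-fold value of small nucleolar RNA per mature read only mirrors the 1.81-fold lower mature share (its own share was 0.117% and 0.116%), and a lower RNA quality in all siRNA libraries would go with the groups. An effect of TINCR loss or of the cells' state on RNA cleavage stays open and untested.

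The second pattern is the fall of let-7a, b, c, d and e but not, relative to other miRNAs, of let-7f, g, i and miR-98. Scaled by all reads these 4 were at −0.89, −0.88, −0.98 and −0.66, where the median of all tested miRNAs was −0.68. The lower mature share sets that general shift. Scaling applies 1 factor per library, which cancels in the log2 ratio of the 5 lower to the 4 other members. This ratio changed by −1.28, but the members were picked by their fall in these libraries, so it restates the inequality and tests no cause. Reads moved to the 4 other members are argued against within that split, as the summed CPM of these 4 changed by −15442.9, not upward. Lower transcription of the genes stays open. Relative to other miRNAs the 3p arms had a median of 0.20, where the 5 lower 5p arms ran from −1.86 to −1.10. Scaled by all reads the 3p median was −0.48 and the 5p arms ran from −2.54 to −1.78. The 3p arms thus lay above the lower 5p arms in either scaling, but the let-7 precursor family was 6.53-fold lower per all reads. The 4 members that did not fall differ from let-7a at position 11 or 12 (G12A in let-7f, G12T in let-7g and let-7i, G11A in miR-98), while the lower members differ elsewhere (A17G and A19G in let-7b, A19G in let-7c, T1A and T16C in let-7d, T9G in let-7e). Fisher's exact test gave p = 0.167 after multiplication by 21 pairs of neighbouring positions, the smallest it can give with 5 and 4 members, so it could not have passed and a role of these bases stays open, as does an effect of TINCR loss.

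The third pattern is the set of reads placed in the last exon of TINCR, at least 1374 reads in every siRNA library and none listed in NC, in data outside the miRNA comparisons. For these 12 entries a minimum of 10 reads for listing is argued against, since the lowest siRNA library stood 14.51-fold above the most that NC could hold unlisted. Whether NC held reads at this position in another read class cannot be told. A rise of these entries by the common factor of all repeat reads, 1.83-fold, is argued against as well. That average cannot exclude a larger rise at a single repeat, and it comes from a class that does not hold the predicted piRNA reads. The siRNAs' own molecules stay open, because all 12 entries carry the same position and the 11 listed in both siRNA groups cannot separate them. Of all predicted miRNA and piRNA entries, 70 were listed in every siRNA library and in no NC library (10 of them at TINCR) and 30 the other way round, and the TINCR entries had the most reads of the 70 (mean 5606, against 506 at the next locus, on chromosome 21). As a hypothesis, these may be fragments of TINCR transcripts left after siRNA-guided cleavage, and neither the siRNA sequences nor the read sequences are in the files to test it.

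miR-619-5p is given because it passed the direct test between the siRNAs, with a log2 difference of 2.09. An Rfam entry described as a CRISPR RNA direct repeat element rose 302.1-fold in RPM (3 to 10 reads in NC libraries, 1067 to 2888 in siRNA libraries), and the files do not show which sequence is counted there. A predicted miRNA on chromosome 1 (144419237 to 144419285, plus strand) rose 56.7-fold, from 56.7 to 3214 RPM. Another on chromosome 12 (98504251 to 98504322, plus strand) rose 8.70-fold. On chromosome 16, a predicted miRNA within FBXO31 (87384075 to 87384119, minus strand) rose 24.98-fold and 1 within PHKB (47504815 to 47504879, plus strand) rose 3.85-fold. Each of these 5 rises had an exact permutation p of 0.0119.

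Other splits of the libraries were run for each count. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05: the real count was 38 for Si-TINCR-1 (1 split as large, highest other 1), 49 for Si-TINCR-2 (1 split, highest other 0) and 1 between the siRNAs (2 splits, highest other 1). For both siRNAs as 1 group, 45 miRNAs were called. Only the real split of the 84 gave as many, and the highest other gave 5. This sets the count apart from other splits of these 9 libraries. It cannot exclude a chance difference between cultures or batches, since the labels do not state that the replicates were separate cultures. The 2 lists were matched by 13 of 84 splits (highest other 2), so chance is not excluded for the number of lists. For the 29 shared calls, only the real split of the 100 gave as many (highest other 22), with the same limit. The real count was 21 without Si-TINCR-2 replicate 2. For the correlation of 0.76 it was 4 of 100, a share under 0.05, but the highest other was 0.85 and the value of 0.60 without Si-TINCR-1 replicate 1 lay within the range of simulations without an effect.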

How the results depend on the processing

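Scaling by whole library totals and fry without miR-205-5p were chosen after seeing the data, and the other alternatives were planned. The scaling shifted the median log2 fold change by −0.67 for each contrast with NC, which turns most miRNAs into falls: 289 were called for Si-TINCR-1 (19 higher), 326 for Si-TINCR-2 (23), 395 for the mean (24) and 220 with both siRNAs (16), sharing 35, 41 and 48 calls with those reported for the first 3. The lower share of mature reads sets this shift by construction. Named positive values that became negative and passed the test under it for the mean of both siRNAs were miR-7-5p (−0.36), miR-125b-5p (−0.66), miR-128-3p (−0.48), miR-27a-3p (−0.60), miR-542-5p (−0.59), miR-98-5p (−0.66), miR-34a-5p (−0.50), miR-486-5p (−0.58), miR-143-3p (−0.52), miR-15b-5p (−0.44), miR-181a-5p (−0.57) and miR-429 (−0.55), joined by the arms let-7a-3p (−0.58) and let-7c-3p (−0.60), while others turned negative without passing (miR-24-3p, −0.59). No other alternative reversed a named value that passed in either setting, though let-7f-5p (0.23) and let-7g-5p (0.07) were positive without NC replicate 1. Without a filter, 2 miRNAs differed between the siRNAs, the correlation was 0.57 and 4 lists passed (the cause was not tested). With a mean of at least 10 CPM, where fewer miRNAs were tested, 25 were called for Si-TINCR-2, 31 for the mean and 19 with both, and the correlation was 0.90. With the replicate number as a block, 25 were called for Si-TINCR-1 instead of 38 (the cause was not tested). Between the siRNAs, DESeq2 called 10 and a fit of only the 6 libraries 5 (the cause was not tested), and with an estimated correlation 0 lists passed. By fry 5 lists passed, and 3 with miR-205-5p left out. With 1 library left out, counts ran from 26 to 41 for Si-TINCR-1, 28 to 47 for Si-TINCR-2, 35 to 51 for the mean, 21 to 32 with both and 0 to 2 between the siRNAs, lists from 2 to 4 and the correlation from 0.60 to 0.83, with fewer samples in each fit. The counts beyond 1.5 times were 30 (Si-TINCR-2) and 35 (mean) without NC replicate 3, 29 and 28 (Si-TINCR-2) without Si-TINCR-2 replicate 1 and 2, 0 (between the siRNAs) without Si-TINCR-1 replicate 1 or 2, 2 without NC replicate 1 or 3 or Si-TINCR-1 replicate 3, and 4 lists without NC replicate 2 or 3, and the correlation was 0.60 without Si-TINCR-1 replicate 1. Of the reported calls, any single such fit kept 25 to 33 of 38, 26 to 44 of 49 and 35 to 43 of 53. Those kept in every such fit numbered 22, 22 and 32, and 0 of the 1 between the siRNAs. Of 1475 values of single named miRNAs with 1 library left out, 1371 kept their side of the threshold, 100 fell out and 4 came in, with no change of sign among called values. RLE factors, TMM without the 5 most abundant miRNAs and summed duplicates left every count within 1.5 times. Depth limits miRNAs near the floor of 3 counts, 0.255 to 0.530 CPM.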

Other observations

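The level of several miRNAs that mark breast cell types can be read from these libraries apart from any comparison. miR-222-3p (12795 CPM over all libraries), miR-221-3p (2465 CPM) and miR-31-5p (2041 CPM), miRNAs that are higher in basal than in luminal breast cells, exceeded miR-200c-3p (297 CPM), miR-141-3p (11.03 CPM) and miR-375 (2.16 CPM), which mark epithelial and luminal cells. miR-34a-5p, a target of p53, stood at 14067 CPM. Relative to other miRNAs only miR-375 of these 7 passed edgeR's test with an siRNA, but when libraries were scaled by all their reads miR-34a-5p, miR-200c-3p, miR-221-3p, miR-222-3p and miR-31-5p also fell with 1 or both siRNAs. These miRNAs are a selection of markers, and not every marker of basal cells was high: miR-205-5p, a miRNA of basal mammary cells, stood at 5.33 CPM in NC. No library of another line was available for comparison, so the identity of the cells was not tested.

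The let-7 precursor family in Rfam, counted apart from the mature miRNAs, went from 106 ± 26.8 RPM in NC to 16.2 ± 6.99 over the 6 siRNA libraries (exact permutation p = 0.0119). A predicted miRNA on chromosome 22 (11249738 to 11249828, minus strand), which overlaps a 5.8S ribosomal RNA gene, was 4.41-fold lower with the siRNAs (exact permutation p = 0.0119). Both were chosen after their values were seen.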
